A study of Mus musculus with 4 samples.

How the data were processed

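RNA from liver and periodontal tissue of wild-type mice, untreated or with silk ligatures on the second maxillary molars for 14 days, was isolated with RNAiso plus, treated with DNase, enriched for polyadenylated RNA and sequenced with 150-bp paired-end reads on a NovaSeq, per the labels' protocols. The submitters' processing notes name Trim Galore, HISAT2 and the mm10 genome build, with no versions. Per the file headers, reads in exons of both strands were then summed per gene with HOMER's analyzeRepeats.pl on 16 tag directories, with transcripts condensed to genes and no option for raw counts, and compared with getDiffExpression.pl over all pairs of groups. The 8 libraries of the 4 labelled groups were analysed here.

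The deposited library values are described in the column names as reads normalized to 10000000 mapped reads. The values themselves lie on a log2 scale, per the deposited table: they run from -2.33 to 20.03, include negative values, and are exactly 0 in all libraries for 4205 of 25124 genes. Low values are drawn together across libraries, as a regularised log does, so changes of weakly expressed genes are understated. Their spread between libraries is drawn together too: in the liver controls the SD was 0.0050 for Pnlip and 0.0069 for S100a8. P-values of genes near the floor may therefore not measure a real spread between libraries. A number in brackets in each column name is not explained in the sources used here. The authors' deposited log2 fold changes were turned in sign where needed so that they read as ligature minus control. The authors' deposited p-values and adjusted p-values come from a test whose name is not given in the sources used here. 1 cell of the authors' fold changes (Myl7 in periodontal tissue) was damaged and left out.

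Each GEO sample lists 2 library codes, which gave 2 libraries per group. The libraries were mapped to groups by those codes. The labels give no pairing, batch, litter, sex or time of day. The file is titled circadian, and the command in its header names each group with the number 7 or 19, 2 libraries each, which the sources used here do not explain. In the order of that command all 8 libraries analysed here bear the 19, and the libraries with the 7 were not analysed here. With 2 libraries against 2, the smallest two-sided p of an exact permutation test is 0.333, so single values were not tested that way. The sum of unlogged values per library was 6739380 to 12390372, which is not the number of reads, so depth is unknown and no counting interval is given.

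The test fixed before the data were examined assumed read counts and a count model. The deposited values are not counts, so that test was replaced by limma's moderated test on the log2 values as deposited, with a trend of the prior spread with the level, in each tissue separately. Genes were tested if they reached 3 on the log2 scale (8 once unlogged) in at least 2 libraries. P-values were adjusted by Benjamini-Hochberg and 0.05 was the threshold. The filter was set after the values were seen, and the trend was chosen after the counts of genes with and without it had been seen. The interaction was the difference of the ligature effects in 1 model over all 8 libraries, without a block. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9, were used.

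The 38 gene lists were fixed before the data were examined. Some genes are in more than 1 list, so the results of the lists are not independent of each other. Of their 557 symbols, 12 were not matched to the table and 2 were matched by an older or alternative symbol. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. In periodontal tissue 36 lists and in the liver 33 lists were tested. No list passed with an estimated correlation, where the lowest adjusted p was 0.603 in periodontal tissue and 0.352 in the liver and 1 and 2 lists were under 0.05 without adjustment. In fry 3 lists passed in periodontal tissue (clock outputs, lower, 0.016, osteoclast genes, higher, 0.027, and cell cycle genes, higher, 0.032) and 1 in the liver (interferon-stimulated genes). These tests ask for a shift in 1 direction. The version of fry that asks for changes in either direction passed for most lists in both tissues and was not used to call lists.

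The genes named in the text follow a rule fixed before the data were examined. For each tissue it takes the 12 largest rises and the 12 largest falls among genes past the threshold. These genes must have libraries that do not overlap between the groups and a mean unlogged value of at least 50 in the higher group. Antigen receptor segments and predicted or clone-named genes are left out. The rule adds up to 4 members with the smallest p from each list, every core clock gene, and the 10 genes with the smallest p in the interaction. Not every gene it allows is given, and a few are not reported here. Members named beyond it, as in full lists of those that passed, and the genes shared by both tissues were chosen after their values were seen.

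The method was tested on simulated data made from these libraries, in 10 runs. In the liver (12751 genes) it recovered 52.5% of genes changed by a log2 size of 1 and 85.5% at a size of 2, with 6.12% false calls. In periodontal tissue (14942 genes) the shares were 37.8% and 81.5%, with 4.41% false calls. In the interaction (15638 genes) it recovered 59.9% at a size of 2, with 4.62% false calls. A raised list was called in 10 of 10 runs in each tissue and an unchanged list in 0 of 10. The simulated genes were drawn independently of each other, with spreads from limma's own fitted trend, so these runs cannot test those assumptions. In the real lists the estimated correlation reached 0.908 for skeletal muscle markers in periodontal tissue and 0.991 for pancreas markers in the liver.

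Alternatives were other filters, leaving out each library, all 8 libraries in 1 model, other thresholds, and, added after the data were seen, median centring, quantile normalization, removal of a transcript length trend (a loess curve per library, span 0.5), no trend or a robust prior in limma, and the authors' deposited adjusted p-values. Reads shared by near-identical genes, such as the Mup and hemoglobin genes, were assigned by the authors' counting in a way not given in the sources used here.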

Results

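Gene expression was compared between mice with ligature-induced periodontitis and untreated mice in the periodontal tissue, where the ligature was placed, and in the liver. In this model a silk thread tied around the second maxillary molars holds dental plaque against the gum and causes inflammation and loss of the bone that carries the teeth. The ligatures stayed in place for 14 days, and all mice were wild type. Polyadenylated RNA was sequenced with 150-bp paired-end reads. The labels give 4 groups, liver and periodontal tissue with and without ligature, and list 2 libraries for each, 8 in all. Nothing states that the libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

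The deposited values lie on a log2 scale and are described by their column names as reads normalized to 10000000 mapped reads. In all 25124 genes were listed. Read totals were not used here because the file holds normalized values only, so the sequencing depth of each library is unknown. Within a group, the 2 libraries differed by an SD of 0.205 to 0.387 on the log2 scale among genes with values between 10 and 12. Changes are given as ligature minus control on the log2 scale, group values as mean ± SD with n = 2, and positions on mm10 as listed in the file. Adjusted p-values are from limma with Benjamini-Hochberg adjustment. A sum over a gene counts reads in all of its exons on both strands, so overlapping and antisense genes were not separated.

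In periodontal tissue, the question was which genes differ where the ligature was placed. Il1b, the inflammatory cytokine interleukin 1 beta (NM_008361, chromosome 2, 129364578 to 129371139, minus strand), rose from 6.82 ± 0.58 to 10.54 ± 0.11 (SD, n = 2), a 13.1-fold higher level (log2 change 3.72, SE 0.24, adjusted p = 0.0059). Saa3, a serum amyloid A gene expressed in inflamed tissues (NM_011315, chromosome 7, 46711998 to 46715676, minus strand), rose from 4.69 ± 0.46 to 10.10 ± 0.92 (log2 change 5.41, SE 0.40, adjusted p = 0.0059). Ptgs2, the inducible cyclooxygenase, rose by a log2 change of 4.43 (adjusted p = 0.019), and Acod1, which makes itaconate in activated macrophages, by 4.17 (adjusted p = 0.015). Sost, which encodes the osteocyte protein sclerostin, an inhibitor of bone formation (NM_024449, chromosome 11, 101962458 to 101967015, minus strand), fell from 6.82 ± 0.47 to 4.81 ± 0.22 (log2 change -2.01, adjusted p = 0.026).

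Of 14942 genes tested in periodontal tissue, 115 rose and 50 fell at an adjusted p under 0.05. The log2 change was at least 1 in size for 94 of the rises and 37 of the falls. The authors' deposited table gave 371 genes at an adjusted p under 0.05, 214 higher and 157 lower with ligature, and all 165 genes were among them with the same direction. No gene passed without a filter on low values (2650 at an unadjusted p under 0.05) or in limma without a trend of the spread with the level (2199 at an unadjusted p under 0.05), 13 passed a test against a fold of 1.5, and 339 passed with a robust prior. Leaving out 1 library also moved the balance of rises and falls: without ligature library 1 it was 91 up and 83 down, without ligature library 2 222 and 256, without control library 1 64 and 29, and without control library 2 53 and 8. With all 8 libraries in 1 model Acod1, Gp2, Mmp3, Cd14, Csf3r, Sost, Cnga2, Rhag, Maats1, Ccdc194, Nes and Bhlhe40 did not pass (adjusted p 0.0586 to 0.345).

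Inflammatory cytokines and chemokines were the list with the most rises over all genes tested in periodontal tissue. Of 22 tested members, 9 rose and none fell over all genes tested, and 13 rose adjusted over the list alone. The 9 were Il1b, Il6, Ccl7, Ptgs2, Csf3, Cxcl5, Osm, Cxcl2 and Cxcl3. Osm, a cytokine of the interleukin 6 family, rose by 3.25 (adjusted p = 0.015), and the neutrophil-attracting chemokines Cxcl3 and Cxcl5 rose by 1.98 and 1.97 (adjusted p = 0.0059 and 0.0078). The list had a median log2 change of 1.95 (camera, adjusted p = 3.8e-15), but adjusted p = 0.603 with an estimated correlation between its genes. Not every cytokine passed: Tnf was 0.41 higher (SE 0.32, adjusted p = 0.585) and Il1a 0.33 higher (SE 0.33, adjusted p = 0.691). Cxcl5 no longer passed when either control library was left out.

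Among the genes with the largest rises were others linked to the innate immune response. Nlrp3, the sensor protein of an inflammasome that processes interleukin 1 beta, rose by 2.81 (adjusted p = 0.017), and Il1rl1, the receptor for interleukin 33, by 3.18 (adjusted p = 0.018). Mmp3, the matrix protease stromelysin 1, rose 7.92-fold (log2 change 2.99, adjusted p = 0.0059). Other large rises were the small proline-rich gene Sprr2i (4.62), the casein gene Csn1s1 (4.29) and Gp2 (3.15), which encodes a glycoprotein of secretory and epithelial cells. With a robust prior the adjusted p became 0.0932 for Saa3, 0.206 for Ptgs2, 0.0763 for Il1rl1 and 0.194 for Gp2. Nlrp3 failed without control library 2.

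Markers of neutrophils and macrophages did not pass as lists in periodontal tissue in the camera test, which asks for a shift in 1 direction. In fry's test of changes in either direction, which most lists passed, their adjusted p was 0.011 and 0.0053. Of 15 neutrophil markers, 1 rose over all genes and 4 adjusted over the list alone. The 1 was Csf3r, the receptor for granulocyte colony-stimulating factor (log2 change 1.69, adjusted p = 0.0078). Their median change was -0.17 while their mean was 0.17, and the test pointed up (adjusted p = 0.416). S100a8, which encodes a subunit of calprotectin, had a change of 0.97 that did not pass in limma (adjusted p = 0.056), from 12.64 to 13.62. S100a9 was 0.80 higher and did not pass either (adjusted p = 0.111). Both passed in the authors' deposited table (adjusted p = 1.9e-08 for S100a8 and 5.1e-06 for S100a9). Of 15 macrophage and monocyte markers, 1 rose, Cd14, the lipopolysaccharide co-receptor (log2 change 1.39, adjusted p = 0.0060), 1 rose and 2 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.357). Of 8 tested complement and acute phase genes, Saa3 and Orm1 rose, also adjusted over the list alone (Orm1 by 2.15, adjusted p = 0.0060), and the list did not pass (adjusted p = 0.245). Of 15 matrix proteases, Mmp3 rose and Adamts1 fell by 0.82 on the log2 scale, 6 rose and 2 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.257). Adamts1 did not pass without either control library.

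Bone genes mostly did not pass one by one in limma. Of 16 osteoclast genes, none passed over all genes tested, while 9 rose and 1 fell adjusted over the list alone, with a median change of 0.61. The list was higher in the camera test (adjusted p = 7.9e-05), but adjusted p = 0.603 with an estimated correlation. In fry, which asks whether the genes of a list move one way on balance, it had an adjusted p of 0.027. Dcstamp, needed for osteoclast fusion, was 1.16 higher (adjusted p = 0.056) and Acp5, tartrate-resistant acid phosphatase, 0.71 higher (adjusted p = 0.066). Of 16 osteoblast and bone matrix genes, 1 fell over all genes tested, Sost, and 5 fell adjusted over the list alone, with a median change of -0.17 (camera, adjusted p = 0.0015, 0.603 with an estimated correlation, and 0.157 in fry). The 2 lists were not compared in a test. The osteocyte genes Mepe and Dmp1 had changes of -0.67 and -0.62 that did not pass (adjusted p = 0.063 and 0.064). In the authors' deposited table Mepe, Dmp1 and Acp5 passed (adjusted p = 0.024, 0.0080 and 0.00042), and Dcstamp did not (0.051). Sost did not pass without control library 2.

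**Figure D1:**
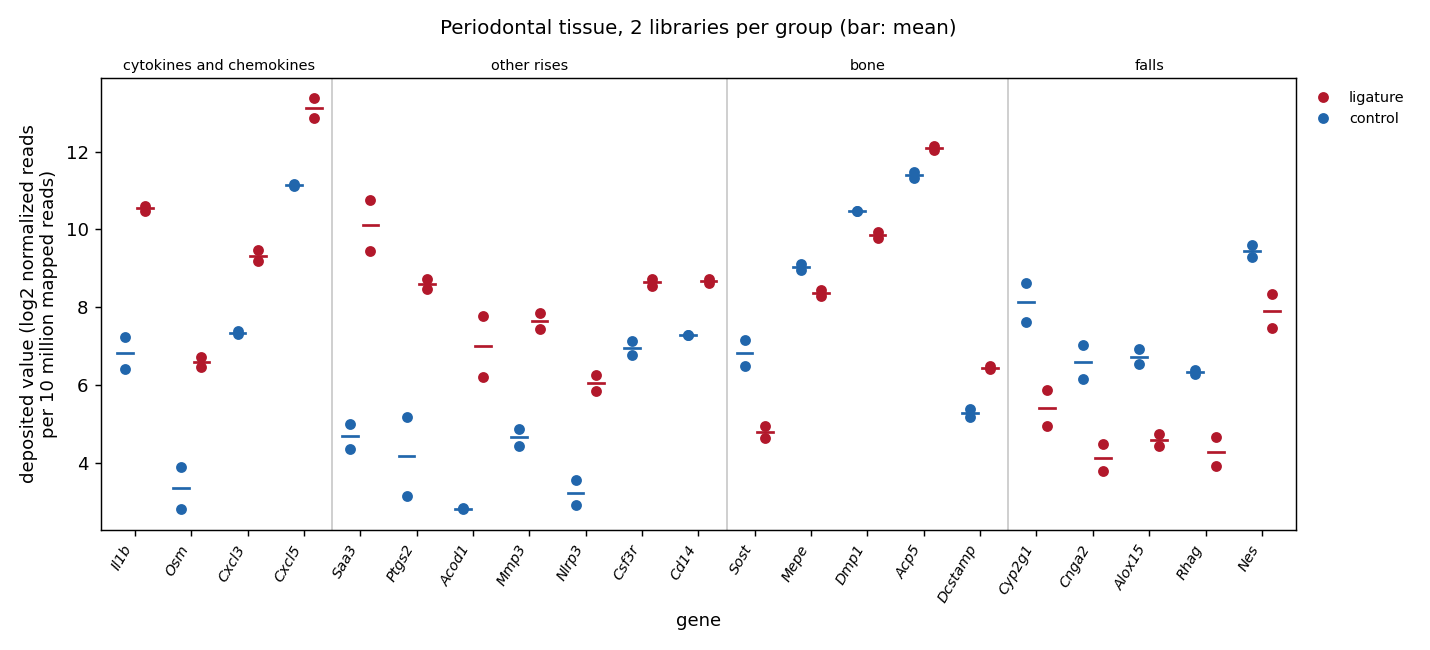
Deposited values of named genes in periodontal tissue, on a log2 scale and labelled as reads normalized to 10000000 mapped reads. There is 1 dot per library (2 per group, red for ligature, blue for control) and a bar at the group mean. Il1b lies at 10.46 and 10.61 with ligature and at 6.42 and 7.23 without. Sost lies at 4.66 and 4.97 with ligature and at 6.49 and 7.16 without. Acp5, Dcstamp, Mepe and Dmp1 did not pass in limma, while Acp5, Mepe and Dmp1 passed in the authors' deposited table.

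Several genes that fell in periodontal tissue are known from the nose and from cilia. Cyp2g1, an olfactory cytochrome P450, fell by 2.70 on the log2 scale (adjusted p = 0.028), Cnga2, the olfactory cyclic nucleotide-gated channel, changed by -2.45 (adjusted p = 0.031), and the cilia-associated gene Maats1 by -1.84 (adjusted p = 0.022). Dcdc2a, also linked to cilia, fell by 2.30 on the log2 scale (adjusted p = 0.024). Of 12 drug-metabolising cytochrome P450 and conjugation genes, 2 fell over all genes, among them Sult1a1 (-0.93), and 5 fell adjusted over the list alone (camera, adjusted p = 0.00047, 0.0593 without a filter, and 0.603 with an estimated correlation). The median of 12 further olfactory neuron markers, a list added after the falls of Cyp2g1 and Cnga2 had been seen, was 4.26 and 3.62 in the ligature libraries and 5.16 and 6.45 in the control libraries. Further falls were Alox15, a lipoxygenase (-2.13), the erythroid gene Rhag (-2.05), the carbonic anhydrase gene Car1 (-1.65), Cyp4b1 (-1.57), Ccdc194 (-1.56) and the intermediate filament gene Nes (-1.55, adjusted p = 0.048). Cyp2g1, Cnga2 and Car1 did not pass without control library 2, Cyp2g1 not with a robust prior (adjusted p = 0.127), and Dcdc2a, Maats1, Sult1a1, Alox15, Rhag, Cyp4b1, Ccdc194 and Nes without either control library. Nes also failed with every scaling tried, at adjusted p = 0.0537 with median centring, 0.0508 with quantile normalization and 0.0603 with the transcript length trend removed.

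Markers of muscle and red blood cells also differed between the periodontal groups. All 15 skeletal muscle markers were higher with ligature, none passed over all genes and 13 rose adjusted over the list alone, with a median change of 1.64 (camera, adjusted p = 3.6e-08, and adjusted p = 0.688 with an estimated correlation). Their median value was 10.9 and 9.59 in the ligature libraries and 8.98 and 7.82 in the control libraries. All 8 erythroid genes were lower, none over all genes and 8 adjusted over the list alone, with a median change of -1.26 (camera, adjusted p = 1.2e-07, and adjusted p = 0.683 with an estimated correlation). Their median value was 8.82 and 9.79 with ligature against 10.4 and 10.8 without. The inflammatory and bone genes above were measured in these same libraries.

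Of 19 core circadian clock genes tested in periodontal tissue, 1 rose, Bhlhe40 (log2 change 0.70, adjusted p = 0.039), also adjusted over the list alone, and the list did not pass (adjusted p = 0.242). The other 18 lay between -0.53 (Hlf) and 0.10 (Bhlhe41), with Per1 at -0.37, Per2 at -0.33, Arntl at -0.12, Clock at -0.14, Nr1d1 at -0.16 and Dbp at -0.08. Bhlhe40 did not pass without either control library, nor with quantile normalization (adjusted p = 0.0685). Of 13 genes listed as clock outputs in liver, 1 fell, Fkbp5, a glucocorticoid-induced gene (-0.89, adjusted p = 0.018), and 3 fell adjusted over the list alone (camera, adjusted p = 0.00056, and adjusted p = 0.603 with an estimated correlation). Fkbp5 did not pass without either control library.

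In 4 further lists no gene passed over all genes in periodontal tissue, yet the camera test placed them higher. They were immediate early genes (2 of 15 up adjusted over the list alone, adjusted p = 0.00056), fatty acid oxidation and PPAR alpha targets (4 of 18 up and 1 down, 0.016), hepatic stellate and fibrosis genes (5 of 12 up and 1 down, 0.016) and endothelial markers (5 of 12 up and 1 down, 0.018). With an estimated correlation the adjusted p was 0.709, 0.709, 0.688 and 0.603. In camera each also failed without single libraries: immediate early genes without control library 1 (0.0991), PPAR alpha targets without ligature library 1 (0.0553) or control library 2 (0.262), fibrosis genes without ligature library 1 (0.0727) or a filter (0.069), and endothelial markers without ligature library 2 (0.101) or control library 1 (0.0856). The other 25 of the 36 lists did not pass, with a lowest adjusted p of 0.083 for the 21 keratinocyte differentiation genes, of which none passed over all genes and 3 rose and 1 fell adjusted over the list alone. Beyond those already described, 1 member passed in 3 of them: Ifi27l2a fell among 17 interferon-stimulated genes (-1.43), Trf among 5 hepatocyte identity genes (-0.92), and Cyp7b1 rose among 5 bile acid genes (1.61). Adjusted over the list alone, 3 interferon-stimulated genes fell, 2 hepatocyte genes rose and 1 fell, and 1 bile acid gene rose and 1 fell, while Trf and Cyp7b1 did not pass over all genes without either control library. No member passed over all genes in the lists of adipocyte, B and plasma cell, cholangiocyte, Kupffer cell, mast cell, nerve and Schwann cell, salivary gland and T and NK cell markers, nor in those of cell cycle, cholesterol synthesis, gluconeogenesis, heat shock, lipogenesis, NRF2, periodontal ligament and sex-biased liver genes. Adjusted over the list alone, 2 adipocyte markers fell, 1 B and plasma cell marker of 9 rose and 4 fell, 1 nerve marker fell, 4 salivary gland markers of 9 rose and 1 fell, 1 T and NK cell marker, 1 gluconeogenesis gene and 2 periodontal ligament genes rose, 1 sex-biased gene rose and 1 fell, and in the other 8 of these lists none passed. The bile acid list had a median of -0.48 and pointed up in fry, the sex-biased list pointed down in camera and up in fry, and the Kupffer list had a median of -0.10 while its test pointed up.

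In the liver, the question was which genes differ in an organ away from the ligature. The largest falls were in the major urinary protein genes, abundant male-biased products of hepatocytes. Mup7 (NM_001347129, chromosome 4, 60066469 to 60070475, minus strand) fell from 16.52 ± 0.07 to 13.25 ± 0.35 (SD, n = 2), a log2 change of -3.28 (adjusted p = 6.6e-06). Cyp2b9, a female-biased cytochrome P450 (NM_010000, chromosome 7, 26173409 to 26210660, plus strand), rose from near the floor, 2.37 and 0.64 in the control libraries, to 9.86 and 10.40 (log2 change 8.63, SE 0.46, adjusted p = 3.9e-06). S100a8, a neutrophil marker (NM_013650, chromosome 3, 90669071 to 90670034, plus strand), rose from 2.09 and 2.10 to 6.99 and 6.22 (log2 change 4.50, adjusted p = 0.00033). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (NM_007824, chromosome 4, 6265612 to 6275632, minus strand), changed by -1.44 (adjusted p = 0.019).

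Of 12751 genes tested in the liver, 295 rose and 247 fell at an adjusted p under 0.05. The log2 change was at least 1 in size for 137 rises and 81 falls. The authors' deposited table gave 445 genes, 215 higher and 230 lower with ligature, and 367 of the 542 were among them, all with the same direction. Named genes that did not pass in the authors' table included Jchain, Cfd, Retnlg, Cyp2a4, Igfbp1, Elovl3, Hlf, Acacb and Dgat1. Of the named pancreas genes, only Pnlip and Cela3b passed there (adjusted p = 0.041 and 0.042). The filter and the model of the spread set the count: 60 genes passed without a filter (5 of them among the 542), none in limma without a trend of the spread with the level (2277 at an unadjusted p under 0.05), 48 against a fold of 1.5, and 1439 without ligature library 1 (652 up and 787 down). With all 8 libraries in 1 model 17 of the named genes did not pass, among them Cxcl13, Ppargc1a, Tat, Elovl3, Cyp2a4, Cyp4a31 and Hlf (adjusted p 0.0503 to 0.345). Shorter transcripts were higher in the ligature livers, with a Spearman correlation across genes of -0.222 between change and transcript length (genes are not independent replicates) and all 77 ribosomal protein genes above 0. Single libraries carried most of this trend: the correlation of a library's deviations with length was -0.274 in ligature library 2 and 0.252 in control library 2, against -0.038 in ligature library 1 and 0.104 in control library 1. With that trend removed, an alternative added after seeing the data, 166 genes rose and 250 fell in place of 295 and 247, and 368 were among the 542.

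Of the 22 Mup genes listed, 19 were tested, and 16 fell and none rose, with a median change of -2.89. The falls included Mup17 (-4.44, adjusted p = 3.5e-06), Mup2 (-3.87), Mup14 (-3.83, adjusted p = 6.8e-07), Mup15 (-3.51), Mup16 (-3.35), Mup1 (-3.24), Mup11 (-3.16), Mup8 (-3.06) and Mup13 (-2.89). Mup genes are near-identical copies that share reads, and some overlap, so their single values are uncertain. Summed over the family the value was 16.66 ± 0.125 with ligature and 18.19 ± 0.00545 without (SD, n = 2), 2.88-fold lower. Mup11 did not pass with a robust prior (adjusted p = 0.157).

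Sex-biased liver genes moved in both directions. Of 15 tested members, 9 fell and 3 rose over all genes, and 10 fell and 3 rose adjusted over the list alone. The test pointed down (camera, adjusted p = 0.00079, 0.323 without a filter, and 0.352 with an estimated correlation), with a median of -1.13 and a mean of -0.12. Because the list holds both male-biased and female-biased genes, that direction depends on how many of each were listed. In fry's test of changes in either direction, which most lists passed, its adjusted p was 0.026. The 9 were Mup7, Mup21, Cyp4a12a, Cyp4a12b, Cyp2d9, Elovl3, Serpina1e, C6 and Bcl6, which are known as male-biased. The 3 that rose, Cyp2b9, Acot3 (log2 change 2.40, adjusted p = 0.00041) and Cux2 (2.43, adjusted p = 0.0094), are known as female-biased. Cyp4a12b fell by 2.15 (adjusted p = 0.00035) and Elovl3 changed by -1.70 (adjusted p = 0.013). Cyp2a4 rose by 2.52 (adjusted p = 0.024). Selenbp2 (-3.47) and Fam107a (-2.59) were the other genes among the 12 largest falls. Elovl3 did not pass with a robust prior (adjusted p = 0.155).

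3 enzymes of bile acid synthesis were lower in the ligature livers. Cyp8b1, a sterol hydroxylase, fell by 1.37 on the log2 scale (12.91 to 11.54, adjusted p = 0.00034), Cyp7b1, the oxysterol hydroxylase of the alternative route, changed by -1.66 (adjusted p = 0.0029) and Cyp7a1 by -1.44. They were the members that passed among 15 bile acid synthesis and transport genes, over all genes and adjusted over the list alone (camera, adjusted p = 0.014, 0.223 without control library 2, 0.188 without a filter, and 0.561 with an estimated correlation). Cyp7a1 did not pass with a robust prior (adjusted p = 0.0871) or with all 8 libraries in 1 model (adjusted p = 0.0688).

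Markers of neutrophils and macrophages were higher in the ligature livers. Of 7 neutrophil markers tested, 6 rose over all genes and 7 adjusted over the list alone, with a median change of 3.50 (camera, adjusted p = 8.6e-09, and adjusted p = 0.352 with an estimated correlation). Besides S100a8 they were S100a9 (4.31), Retnlg (2.86), Cxcr2, Ngp and Lcn2 (1.16), and the control values of all but Lcn2 were below 3. The other 8 of the 15 listed members did not reach the filter on low values, and Mpo, Ly6g and Elane stayed below 3 in all 4 livers. Without the filter, none of the 15 passed over all genes in limma (9 at an unadjusted p under 0.05), 14 lay above 0 with a median of 1.87, and the list was higher (camera, adjusted p = 3.5e-07). Of 14 macrophage and monocyte markers, 8 rose, among them C1qa (0.92, adjusted p = 0.0037) and Lyz2 (1.13), and 1 fell (camera, adjusted p = 3.3e-07, and adjusted p = 0.352 with an estimated correlation). Of 10 Kupffer cell markers, which mark the resident macrophages of the liver, 7 rose, among them the scavenger receptor gene Marco (2.28, adjusted p = 0.0034) and Cd5l (1.02), and C6 fell (-1.13) (camera, adjusted p = 7.2e-06, and adjusted p = 0.352 with an estimated correlation). Adjusted over the list alone, 10 rose and 1 fell among the macrophage markers and 8 rose and 1 fell among the Kupffer markers. T and NK cell markers (none of 9, adjusted p = 0.137) and B and plasma cell markers (1 of 5 up, 0.075) did not pass as lists. Marco, Cd5l and C6 did not pass with all 8 libraries in 1 model (adjusted p = 0.0932, 0.122 and 0.166). These ligature libraries also held pancreas transcripts and higher adipocyte markers.

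Interferon-stimulated genes were higher in the ligature livers as well. Of 17 tested, all lay above 0, 6 rose over all genes (Ifit3, Irf7, Isg15, Gbp2, Rsad2 and Ifi27l2a) and 12 adjusted over the list alone, with a median of 0.74 (camera, adjusted p = 1.8e-08, and adjusted p = 0.352 with an estimated correlation). This was the list that passed in fry (adjusted p = 0.044). Irf7, a transcription factor of the interferon response, rose 2.31-fold (log2 change 1.21, adjusted p = 0.0022). Isg15 rose by 1.08, but not past the threshold with the transcript length trend removed (adjusted p = 0.0508).

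Only some complement and acute phase genes passed in the liver, and in both directions. Of 20 complement and acute phase genes, Itih4 (0.75), Apcs (0.82) and Lcn2 rose and Serpina3n fell (-0.70), over all genes and adjusted over the list alone, and the list did not pass (adjusted p = 0.077). Saa3, raised in periodontal tissue, was 0.59 higher in the liver without passing (adjusted p = 0.225). Apcs did not pass with the transcript length trend removed (adjusted p = 0.0725) nor without control library 2. Itih4 did not pass without either control library and Serpina3n not without control library 1.

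**Figure D2:**
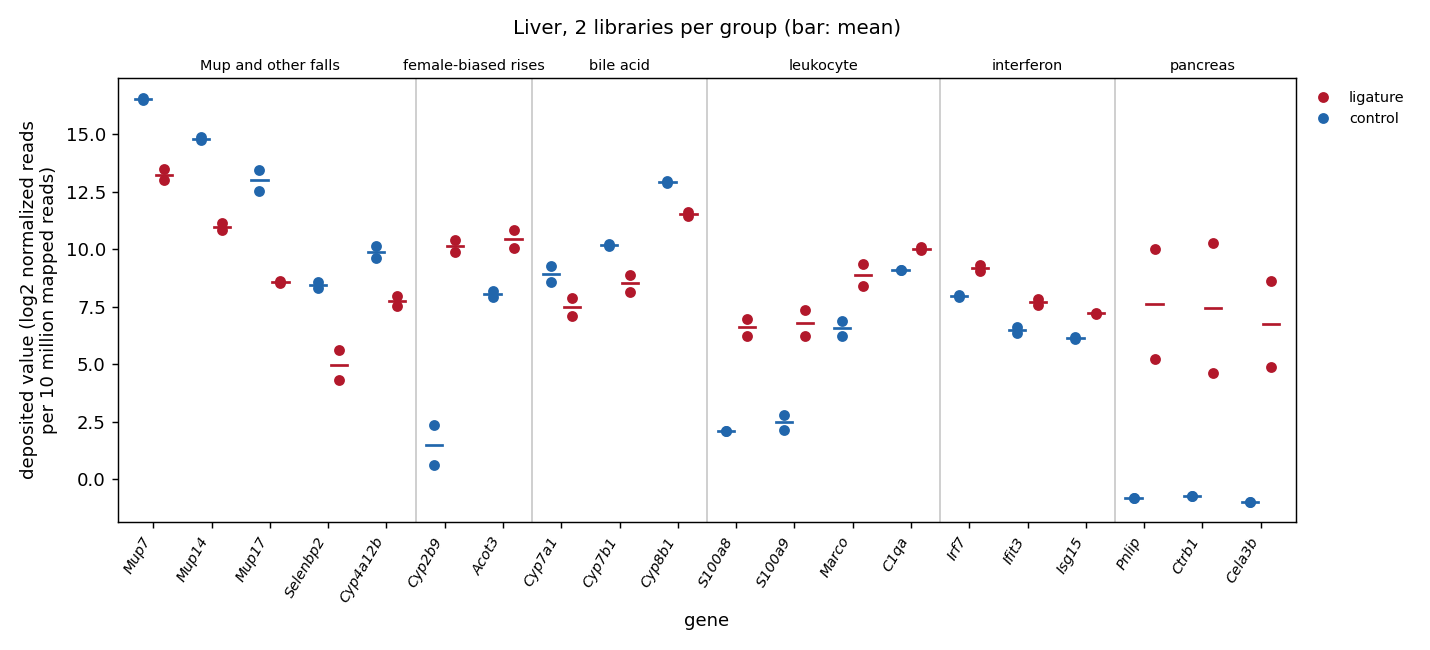
Deposited values of named genes in the liver, on a log2 scale and labelled as reads normalized to 10000000 mapped reads. There is 1 dot per library (2 per group, red for ligature, blue for control) and a bar at the group mean. Mup7 lies at 13.49 and 13.00 with ligature and at 16.48 and 16.57 without, and the pancreas gene Pnlip at 5.23 and 10.02 in the ligature libraries and at -0.80 in both control libraries.

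Metabolic genes of the liver changed in part. Of 14 gluconeogenesis and insulin response genes, 3 fell and 1 rose over all genes and 8 fell and 1 rose adjusted over the list alone (camera, adjusted p = 0.00068, and adjusted p = 0.352 with an estimated correlation). Ppargc1a, a coactivator of fasting genes, fell by 1.10, and Igfbp1 and Tat changed by -1.18 and -0.93. Of 18 clock outputs, Lpin1 (-1.28), Pnpla2 (-0.66), Cyp7a1 and Elovl3 fell and Wee1 rose, with 6 down and 1 up adjusted over the list alone (camera, adjusted p = 0.017, 0.0619 without ligature library 2, 0.110 without control library 2, 0.134 without a filter, and 0.561 with an estimated correlation). Of 21 fatty acid oxidation and PPAR alpha targets, Vnn1 (1.34), Acot1 (1.31), Acot2 and Ehhadh (0.66) rose and Angptl4 and Cyp4a31 (-0.82) fell, with a median of -0.01 and a mean of 0.10, and the list did not pass (adjusted p = 0.725, 5 up and 2 down adjusted over the list alone). Of 18 lipogenesis genes, 1 rose and Acacb (-0.55) and Dgat1 (-0.58) fell (adjusted p = 0.540 for the list, 2 up and 2 down adjusted over the list alone). Igfbp1, Vnn1 and Acot1 did not pass with a robust prior (adjusted p = 0.0897, 0.0921 and 0.103), and Tat, Ehhadh, Acacb and Dgat1 not without either control library. Acacb also failed without ligature library 1 (0.0613) and with every scaling tried (0.0546 with median centring, 0.0802 with quantile normalization, 0.0940 with the length trend removed), and Dgat1 with median centring (0.0549) and quantile normalization (0.0792).

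Of 18 core circadian clock genes tested in the liver, Clock fell and Hlf rose. Clock (NM_001289826, chromosome 5, 76209868 to 76304792, minus strand) changed by -0.59 (adjusted p = 0.036) and Hlf by 0.54 (adjusted p = 0.043), and the list did not pass (adjusted p = 0.374, 1 up and 2 down adjusted over the list alone). The other genes lay between -0.60 (Ciart) and 0.59 (Bhlhe41), with Arntl at -0.39, Per1 at -0.29, Per2 at 0.01, Nr1d1 at -0.32, Rora at -0.46 and Dbp at 0.08. Without ligature library 1, Ciart (-0.99) and Rora (-0.58) passed. Clock and Hlf did not pass without either control library, and Clock not with quantile normalization (adjusted p = 0.0613) or with the transcript length trend removed (adjusted p = 0.0525).

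Transcripts of another organ were present in the ligature livers. Of 10 pancreas markers tested, 9 rose over all genes (camera, adjusted p = 1.4e-11, and adjusted p = 0.352 with an estimated correlation), and 10 adjusted over the list alone. Pnlip, pancreatic lipase, was at 5.23 and 10.02 in the ligature libraries and at -0.80 in both controls, and Ctrb1, a chymotrypsinogen, at 4.61 and 10.27 against -0.74 and -0.73. Cela3b, Try4, Cpa1, Cpb1, Zg16, Clps, Prss2, Try5 and Pnliprp1 made up the rest of the 12 genes with the largest rises after Cyp2b9. With a robust prior Pnlip, Ctrb1, Try4, Cpa1, Cpb1, Prss2 and Pnliprp1 did not pass (adjusted p 0.111 to 0.232), and with quantile normalization Cpb1, Prss2 and Pnliprp1 did not (0.0602 to 0.0674). Ligature library 2 also stood apart in the ribosomal RNA precursor Rn45s, at 16.8 against 13.8 to 14.6 in the other livers. Control library 2 held skeletal muscle transcripts, with Ckm at 7.10, Acta1 at 6.93 and Tnnt3 at 6.86.

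Of the other lists that passed in the liver, 7 were higher and 3 lower. Higher were hepatic stellate and fibrosis genes (Col3a1 and Vim up of 11, adjusted p = 0.0021), periodontal ligament and fibroblast genes (Col3a1 and Fmod up of 12, 0.0030), matrix proteases (none of 8, 0.010), cytokines and chemokines (Cxcl13 up of 8, 0.012), adipocyte markers (Cfd and Lpl up of 5, 0.015) and osteoblast genes (none of 6, 0.037). With an estimated correlation the adjusted p was 0.391 for cytokines and 0.352 for the other 5, and adjusted over the list alone 2, 4, 0, 1, 2 and 1 of their members rose. Some of these lists share genes, so their results are not separate. The fibrosis list shares Col3a1 and Pdgfrb with the fibroblast list, Col1a1 and Col1a2 with the osteoblast list, and Timp1 with the matrix proteases. The lower ones were immediate early genes (none of 12, 0.0035), heat shock genes (Hspa1b down of 19, 0.028) and hepatocyte identity genes (Tat and Cps1 down of 15, 0.032), with adjusted p = 0.352 for each with an estimated correlation and 2, 1 and 2 members down adjusted over the list alone. The seventh higher list was erythroid genes (none of 7 over all genes or adjusted over the list alone, 0.012, and adjusted p = 0.561 with an estimated correlation), and its call rested on control library 2, where the median of the 7 was 8.99 against 9.72 in control library 1 and 9.83 and 10.01 with ligature (0.807 without control library 2). In camera the matrix proteases and cytokines also failed without ligature library 1 (0.0618 and 0.0899), adipocyte markers and immediate early genes without control library 2 (0.0618 and 0.0657), osteoblast genes without ligature library 2 (0.189) or control library 2 (0.158), heat shock genes without ligature library 1 (0.249) or control library 1 (0.269), and hepatocyte genes without ligature library 1 (0.108) or control library 2 (0.143) and with quantile normalization (0.675). Without a filter the erythroid (0.0612), cytokine (0.110), osteoblast (0.171), heat shock (0.0691) and hepatocyte (0.356) lists did not pass either. Col3a1 rose by 1.02, Cxcl13 by 2.83, Cfd by 3.71 and Hspa1b fell by 1.25, whereas Cps1 (-0.98) did not pass without ligature library 2 or either control library, nor with quantile normalization (adjusted p = 0.104).

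The other 14 of the 33 lists did not pass in the liver, with a lowest adjusted p of 0.051 for drug-metabolising cytochrome P450 and conjugation genes, among which Cyp2b9 and Cyp2a4 rose and Cyp2b10 fell (-1.10, adjusted p = 0.048). Jchain rose by 3.15 among 5 B and plasma cell markers, Kdr by 0.58 among 12 endothelial markers and Osgin1 by 0.60 among 10 NRF2 genes, and Cdkn1a fell by 1.07 on the log2 scale among 9 cell cycle genes. Adjusted over the list alone, 4 rose and 1 fell among the cytochrome P450 genes, 1 rose in each of the B and plasma cell and endothelial lists, 3 rose among the NRF2 genes, and 2 rose and 1 fell among the cell cycle genes. The NRF2 list had a median of -0.02 and a mean of 0.09. No member passed over all genes among cholangiocyte, keratinocyte, osteoclast and T and NK cell lists or among 21 cholesterol synthesis genes, and adjusted over the list alone 1 keratinocyte gene rose and no gene of the other 4 lists passed. Cyp2b10 did not pass with any scaling tried (adjusted p = 0.0537 with median centring, 0.0684 with quantile normalization, 0.055 with the length trend removed) or without ligature library 2 or control library 2, nor Osgin1 with the length trend removed (0.0505) or without either control library, nor Kdr without control library 2.

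Whether the ligature effect differed between the tissues was tested as an interaction over all 8 libraries. Il1b rose more in periodontal tissue than in the liver, where it was 0.32 higher without passing (difference of effects 3.40, adjusted p = 0.017), and Cyp7b1 rose in periodontal tissue by 1.61 and fell in the liver (-1.66, difference 3.28, adjusted p = 0.0075). S100a8 rose more in the liver (difference -3.53, adjusted p = 0.0060), from far lower control values than in periodontal tissue. Among the 10 genes with the smallest p, Col18a1 (difference 1.87), Slc38a4 (1.78) and Ankrd33b (2.21) had the higher effect in periodontal tissue and Ifi27l2a (-2.41) in the liver. The others, Cyp8b1 (4.03), Mup14 (3.78), Apoa1 (1.68) and Cyp2b9 (-8.67), were at or near the floor in periodontal tissue. Without periodontal control library 2, S100a8, Cyp7b1, Ifi27l2a, Slc38a4, Apoa1 and Cyp2b9 did not pass (adjusted p = 0.0518, 0.0641, 0.0641, 0.0518, 0.0529 and 0.0542), and without either periodontal ligature library Il1b, Cyp7b1, S100a8 and Cyp2b9 did not. Il1b also failed without liver ligature library 2 (0.0606) and without a trend of the spread (0.0597), and Apoa1 with quantile normalization (0.0674).

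Of 15638 genes in the interaction fit, 96 passed, 51 with the higher effect in periodontal tissue and 45 in the liver. Of the 12076 genes tested in both tissues, 66 passed. The count was 8 without periodontal control library 2, all with the higher effect in periodontal tissue, 15 and 17 without periodontal ligature library 2 or 1, and between 23 and 57 without any other single library. It was 177 without a filter (59 of them among the 96), 47 without a trend of the spread (28 of them among the 96) and 20 against a fold of 1.5.

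Few genes passed in both tissues. Among 12076 genes, 6 rose in both, Clec7a, Fbln2, Fxyd5, Ifitm3, Lilrb4a and Wfdc17, against 1.23 for independent lists (Fisher's exact test, two-sided, p = 0.0014; 201 against 94.6 at an unadjusted p under 0.05, p = 3.6e-27), and none fell in both, against 0.508 (95 against 77.9 at an unadjusted p under 0.05 in limma, p = 0.041, and 5 against 1.28 in the authors' deposited table, p = 0.0091). Clec7a, which encodes the fungal glucan receptor dectin 1, rose by 1.54 in periodontal tissue and by 1.27 in the liver, and Ifitm3, an interferon-induced gene, by 0.75 and 0.62. In 4 genes, among them Ifi27l2a, Inmt and Plekhb1, a fall in periodontal tissue met a rise in the liver, against 0.626 for independent lists (Fisher's exact test, two-sided, p = 0.0033). At an unadjusted p under 0.05 this excess was lost, with 90 genes against 81.6 (p = 0.303), while the authors' deposited table gave 6 against 1.26 (p = 0.0016). Cyp7b1 was the 1 gene with the opposite pair. Fisher's exact test counts genes as independent units, which they are not, so its p-values here do not measure evidence across mice. The change correlated negatively with transcript length in both tissues (Spearman, -0.091 in periodontal tissue and -0.222 in the liver). The overlap was not retested with that trend removed. The genes shared by both tissues were named after their values were seen. Across the 12076 genes, which are not independent replicates, the changes in the tissues correlated with Pearson's r = 0.0553 and Spearman's rho = 0.0661.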

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

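The tests of Xist, hepatocyte genes, the summed Mup value and the pancreas genes below were chosen only after the result was seen, while the islet, olfactory neuron and airway cilia tests were set before theirs, though falls of other cilia genes had been seen.

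The named genes below had a ligature effect that differed between periodontal tissue and liver in a test of the difference itself (limma interaction, all 8 libraries). Values are the periodontal effect minus the liver effect on the log2 scale. Higher in periodontal tissue were Saa3 (4.82), Cyp8b1 (4.03), Mup14 (3.78), Il1b (3.40), Cyp7b1 (3.28), Ankrd33b (2.21), Orm1 (1.99), Col18a1 (1.87), Slc38a4 (1.78), Hspa1b (1.71), Apoa1 (1.68) and Dgat1 (1.08). Higher in the liver were Cyp2b9 (-8.67), S100a8 (-3.53), S100a9 (-3.52), Alox15 (-3.07), Retnlg (-3.06), Ifi27l2a (-2.41), Car1 (-2.41), Isg15 (-2.17), Cyp4b1 (-1.88), Irf7 (-1.38), Trf (-1.32), Adamts1 (-1.10) and C1qa (-1.04). Adjusted p-values ran from 0.00115 for Cyp8b1 to 0.0499 for C1qa. Without a filter 15 of the 25 passed, and 12 without a trend of the spread. C1qa and Irf7 failed in both of these and with median centring, quantile normalization and removal of the length trend. Of these 25 genes, 5 passed without periodontal control library 2, Ankrd33b, Col18a1, Cyp8b1, Il1b and Mup14, so no difference higher in the liver held there, and 7 to 18 passed without any other single library. Cyp8b1, Mup14, Apoa1 and Cyp2b9 were not tested in periodontal tissue, where they lay at or near the floor, so their differences are those of the liver or of values near the floor.

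Male-biased genes fell and female-biased genes rose together in the ligature livers. Female mice are argued against by Xist, at most -0.0298 in the ligature livers, and by Ddx3y, between 9.65 and 10.10 in all 4 livers. A lower share of hepatocyte RNA would move the hepatocyte list about as far as the Mup sum, but its median change was -0.211 (SD of the changes 0.392) against -1.53. Reads moved between Mup copies would leave their sum in place, and it changed by -1.53, with 0 of 19 tested genes up. An effect of the ligature on the regulation of these genes stays open as a hypothesis, as do feeding, stress, age or cage differences between the groups, none of which was tested.

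Pancreas transcripts rose in the ligature livers and may come from pancreas tissue carried over at dissection. The 9 called genes were all higher in ligature library 2 than in library 1, by a median of 4.78 (3.76 to 5.66), the spread that unequal carry-over would leave between libraries of 1 group. All 6 islet markers were below the bound of 3 set before that test, the highest at -0.135 in library 2. This cannot decide whether a piece with islets was carried over. It rests on 1 library and on values at the floor, where weak expression cannot be told from none. Pancreas genes turned on in the liver itself stay open as a biological explanation that was not tested.

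Olfactory genes fell in the ligature periodontal libraries, and less nasal tissue in those dissections is a candidate explanation. Of 12 olfactory neuron markers not looked at before, 12 were lower, with a median change of -1.98, though none passed over all genes in limma (11 at an unadjusted p under 0.05). Of 10 airway cilia markers tested, 10 were lower, with a median change of -1.06, and 1 passed. Whether these cilia transcripts came from nasal cells was not tested. Obp2a, an abundant odorant-binding protein gene of nasal glands, overlapped between the groups, at 15.1 and 16.4 with ligature and 17.3 and 15.7 without, and so was not clearly lower. An effect of the ligature on nasal tissue next to the upper jaw stays open and was not tested.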

How the results depend on the processing

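Median centring, quantile normalization, removal of the transcript length trend, limma without a trend or with a robust prior, and the use of the authors' adjusted p-values were chosen after seeing the data, and the other alternatives before. No called gene turned its direction in any refit in which it was tested, but within each tissue most refits could not have turned one. The libraries of all 165 and all 542 called genes did not overlap between the groups, so leaving out 1 keeps the direction. The other filters, priors and the model over all 8 libraries leave the change itself as it was. That leaves median centring, quantile normalization and removal of the length trend. Of named genes that were not called, Arntl, Clock and Il1a in periodontal tissue and Arntl, Dbp and Per2 in the liver turned their direction, without passing. The cause of the changes below was not tested, except that a test against a fold asks for a larger change and a fit without a library holds fewer samples. The count of genes in periodontal tissue (165) became 0 without a filter, 0 without a trend of the spread, 339 with a robust prior, 13 against a fold of 1.5 and 369 with the authors' deposited adjusted p among the genes tested. In the liver (542) it became 60 without a filter, 0 without a trend, 218 at a log2 change of at least 1 and 48 against a fold of 1.5. The interaction (96) became 177, 47 and 20 without a filter, without a trend and against a fold of 1.5. Of the 96, 59 were among the 177 and 28 among the 47. Leaving out 1 library gave 61 to 478 genes in periodontal tissue, 429 to 1439 in the liver and 8 to 57 in the interaction, with the lone library of a group assumed to vary like the other group. The number of lists called in periodontal tissue (11) was 0 with an estimated correlation and 3 in fry, of which 2 were among the 11 and cell cycle genes were not (9 to 15 without 1 library). In the liver (19) it was 0, 1 and, without a filter, 12 (13 to 21 without 1 library). At an unadjusted p under 0.05 the 6 genes up in both tissues became 201 (94.6 for independent lists, Fisher's exact test, p = 3.6e-27) and the 4 down in periodontal tissue and up in the liver became 90 (81.6, p = 0.303), so the excess of the second was lost. Fisher's exact test treats genes as independent units, which they are not, so the p-values of these overlaps do not measure evidence across mice. With the transcript length trend removed, periodontal tissue had 160 genes, the liver 416 and the interaction 134.

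Of 34 named genes called in periodontal tissue, 32 were tested in all 4 fits without 1 library and 13 passed in all, and of 70 in the liver, 52 were tested in all and 39 passed in all. In periodontal tissue 14 named genes lost their call without control library 1 and 19 without control library 2 (adjusted p 0.0523 to 0.239), and in the liver 10 and 12 (0.0538 to 0.198). No paired analysis was possible because the labels give the libraries no numbers that pair them. With no read counts at hand, other count normalizations (RLE, library size alone), a second count model, voom and the count-based alternatives of the list and overlap tests were not run, and limma's treat stood in for the count version of the test against a fold. Without read totals, what depth limits is unknown.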

Other observations

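The genes named here were picked after their values were seen, so their tests describe these libraries only.

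In periodontal tissue, further single genes passed the same limma test, and no list of them was tested. Small proline-rich genes of the Sprr2 cluster, made by differentiating epithelium, rose beside Sprr2i, Sprr2e by 2.38, Sprr2g by 2.07, Sprr2f by 1.83, Sprr2h by 1.28 and Sprr2d by 1.15, while Sprr2a1 was 2.20 higher without passing (adjusted p = 0.279, but 0.0173 without control library 1). These similar genes can share reads, so their single values are uncertain. Hif1a, the oxygen-sensing transcription factor, rose by 1.22 (adjusted p = 0.012). The endothelial adhesion genes Sele and Selp rose by 2.44 and 1.94 (adjusted p = 0.0059 and 0.010), and the basement membrane collagens Col4a1 and Col4a2 by 1.32 and 1.09. The pattern-recognition genes Trem1, Clec4e and Clec4d rose by 2.20, 1.94 and 1.47.

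In the liver, Egfr, the receptor for epidermal growth factor, fell by 1.08 on the log2 scale (adjusted p = 0.0015), and Lepr, the leptin receptor, and Vldlr, the very low density lipoprotein receptor, rose by 1.62 and 2.60 (adjusted p = 0.0060 for each). Prlr, the prolactin receptor, rose by 0.80 (adjusted p = 0.011). Of 77 ribosomal protein genes, 28 rose and none fell, with a median of 0.483 (SD 0.177), and 5 rose with a median of 0.263 once the transcript length trend was removed. In periodontal tissue none of 78 passed in limma (3 at an unadjusted p under 0.05), with a median of 0.0842.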
